A study of Homo sapiens with 2 samples.

How the data were processed

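RNA from 2 cultures of the human embryonic stem cell line HES2 was compared, 1 expressing PB (the control) and 1 expressing PB-Tfcp2l1ΔCP2. The labels do not spell out PB. Per the labels' protocols RNA was taken with Trizol and sequenced on the BGISEQ-500 platform. Bowtie 0.12.2 and the genome build hg19 are named per the submitters' processing notes, with no role given. The gene counter, the annotation and the test are not given in the sources used here.

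A single table was used, the authors' deposited comparison. Per the file headers it holds, for each gene, a length, an expression value in each library, a log2 fold change, a p-value and an FDR. The authors' expression values are a signal that is never negative, with 2 decimals and a lowest value of 0.01; per the file headers the unit is called only expression, and RPKM, FPKM or TPM cannot be told from the name. Reads recovered as described below, divided by length and depth, follow these values, in part because the search kept only pairs near them. The deposited log2 fold change equals the log2 ratio of the 2 values to within 5.33e-15 and adds no pseudocount. The authors' deposited p-values and FDR compare reads of the libraries, not the conditions. The other deposited measurement is a gene length in bases, per the file headers. The column for the PB-Tfcp2l1ΔCP2 library lacks the word delta in its header and was matched as the only column with Tfcp2l1 in its name. No value column belonged to another sample.

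Every row passes the same thresholds: the largest FDR is 0.000984 and the smallest absolute log2 fold change is 1.00. The table is therefore a list of called genes. The ratio of FDR to p-value is a whole number of tests over a whole rank for 18250 tests (largest distance from a whole rank 2.44e-09), and the highest rank among the listed rows is 3907. So 3482 genes of equal or better rank are not listed and were not analysed here. All 368 rows with a Gene ID matched RefSeq genes (assembly GRCh38.p14), 346 under the same symbol; this table was used for names and neighbours only. No coordinates are given, because hg19, the only build named by the submitters, differs from that of the reference, and the build behind the values is not stated.

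The p-values behave as a 2-sided test of whole reads in 2 libraries (Audic and Claverie). The ratio of library totals, 1.02, was found from rows with no control read and refined on rows with more reads. For each row the pair of whole reads was sought that gives the deposited p-value to a relative tolerance of 5e-06 and fits the value ratio. A single pair was found for 405 of 425 rows (95.3%), none for 15, more than 1 for 1, and for 4 the p-value was too small. Recovered reads had medians of 81 (PB control) and 74 (PB-Tfcp2l1ΔCP2) per row, and 56 rows had fewer than 50 over both libraries. Reads per unit of value and kilobase had medians of 23.0 and 23.5 over 155 rows. The search itself was limited to a range of reads per unit and kilobase, so these medians are no independent check. The recovery was tested on simulated data for this comparison. Of 191 genes changed 8-fold, 89.0% came back exactly, of 191 changed 3-fold, 99.0%, and none came back wrong. The simulated p-values came from the same formula that the search inverts. Each simulated gene also had the same reads per unit and kilobase in both libraries. The simulation thus checks the search in that setting, not whether the authors used that formula. Random lists of 5 genes had a median percentile of 53.1, and a list raised by 6 on the log2 scale was at percentile 100. That shift is larger than any increase among the named genes on that scale (2.95 at most, for CER1). The place of the raised list was therefore all but fixed in advance and is no check on smaller shifts.

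As fixed before the data were examined for normalized values, the comparison is the difference of log2(value + 1), for genes with a value of 1 or more in either library, called at 2-fold. With 1 library per group there is no test across conditions. Folds in the text are ratios of recovered reads divided by the ratio of library totals, with exact conditional binomial (Clopper-Pearson) 95% intervals. These intervals cover counting error only and leave out the spread between cultures. They treat reads as independent, so where reads are not independent molecules the intervals are too narrow even for counting error. Where a library had no read, the fold is a lower bound against 3 counts per library. Gene lists with at least 4 members at a value of 1 or more have a median and its percentile among 10000 random lists of the listed genes matched on mean expression. The named genes are TFCP2L1; the 15 largest and 15 smallest log2 ratios among genes with a symbol and a value of 5 or more; up to 4 members of each list with the largest absolute log2 ratio; and the 5 largest differences in value in each direction. Among the last are gene models without a name, which are not described singly. TFCP2L1 has no value here. Results for 2 genes are not reported here; gene lists, named genes and labelled points leave them out, and the totals of rows keep them. Genes outside this rule, LHX1, GATA5, TNC, EFEMP1, LAMA4 and MATN4 in the report and others in the closing section, were chosen after their values were seen. LHX1 is the remaining listed member of its fixed list.

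The alternatives were another scaling, pseudocounts of 0.5 and 5, no filter and a filter at 5, thresholds of 1.5-fold and 4-fold, the mean in place of the median of a list, FDR thresholds of 0.05, 0.01 and 0.001, and, added after the data were seen, recovered reads, no pseudocount, and the table without unnamed, read-through and shared rows. Overlapping genes, read-through rows (10) and rows that share a place or a near-identical copy with another listed row (16) are uncertain, because the counting is not described. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.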

Results

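Total RNA was sequenced from HES2 cells, an established human embryonic stem cell line, that expressed either PB or PB-Tfcp2l1ΔCP2. By its name the latter carries Tfcp2l1 without a part called CP2; TFCP2L1 is a transcription factor of the CP2/grainyhead family that belongs to the naive pluripotency network. Each group had 1 library, so the differences below have no replicate check and describe these 2 libraries. Both cultures were kept for 2 passages in a 10% KSR medium. It held FGF2 at 10 ng/ml, and Activin A at the same concentration. The comparison asks which genes differ in human embryonic stem cells that express Tfcp2l1ΔCP2. The authors' deposited table lists called genes only. It gives 1 expression value per gene and library, without naming the unit, and no library totals. A ratio of library totals of 1.02 (PB-Tfcp2l1ΔCP2 over PB control) was recovered from the p-values, so that the depths were close to equal.

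The listed genes of the primitive streak (5 of 15, among them the Nodal inhibitor gene CER1) and of the endoderm (4 of 17) were higher in the PB-Tfcp2l1ΔCP2 library. The listed genes of naive pluripotency (3 of 22), the LIF/STAT3 pathway (2 of 12) and glycolysis and hypoxia (2 of 19) were lower. The other members of these lists were not analysed here. CER1 (Gene ID 9350) went from an expression value of 2.43 to 25.4, which was 10.5-fold by recovered reads (95% counting interval 8.11 to 13.7). EOMES (Gene ID 8320), a T-box factor of the streak, went from 0.11 to 3.06, or 31.3-fold (15.6 to 73.2). In the other direction NMU (Gene ID 10874), which encodes the neuropeptide neuromedin U, went from 29.0 to 2.32, or 12.6-fold lower (9.17 to 17.8). Intervals cover counting error only.

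The authors' deposited table holds 425 rows, 201 higher and 224 lower in the PB-Tfcp2l1ΔCP2 library, all at least 2-fold apart. Of these, 368 carry a gene symbol (174 higher, 194 lower) and 57 are gene models without a name. On the log2(value + 1) scale, which shrinks the folds of low genes, 49 genes were at least 2-fold higher and 49 at least 2-fold lower among the 291 with a value of 1 or more in either library. With the libraries scaled to the total of the listed genes the counts were 91 and 21. With median-of-ratios scaling over the listed genes they were 147 and 11. Both factors rest on called genes only, none of which lies within 2-fold. They are therefore no check of the depths, whose recovered ratio was 1.02. TFCP2L1 itself was to be reported first, but it had no row among those used here. The construct could therefore not be checked from the values, and the labels do not give the species of the insert; the groups are named as labelled.

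**Figure D1:**
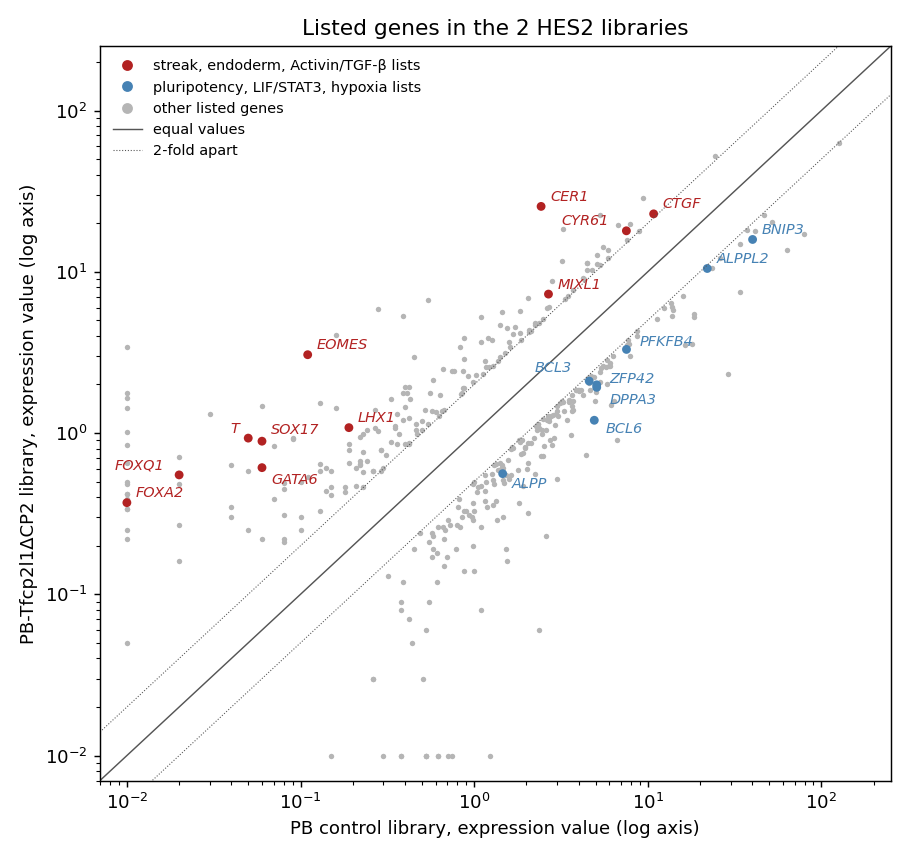
Expression values of the 425 listed genes in the PB control library (x axis, log scale, the authors' unit) and in the PB-Tfcp2l1ΔCP2 library (y axis, log scale, the authors' unit), 1 point per gene. The solid line marks equal values and the dotted lines a 2-fold difference; the 11 red genes of the streak, endoderm and Activin/TGF-β lists lie above the upper dotted line, from FOXA2 at 0.37 to CER1 at 25.4, and the 8 blue genes of the pluripotency, LIF/STAT3 and hypoxia lists lie below the lower one. Points at 0.01 had no recovered read in that library.

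Of 15 primitive streak and mesendoderm genes, 5 were listed and all 5 were higher. MIXL1 (Gene ID 83881), a homeobox gene of the streak, went from 2.68 to 7.27 (2.70-fold, 95% counting interval 2.20 to 3.35). LHX1 went from 0.19 to 1.08 (5.74-fold, 3.30 to 10.7). T, the brachyury gene, went from 0.05 to 0.93 on 3 reads in the control and 53 in the PB-Tfcp2l1ΔCP2 library, or 17.3-fold (5.60 to 86.4). The 4 genes with a value of 1 or more had a median difference of 1.52 on the log2(value + 1) scale. This was at percentile 99.9 among 10000 random lists drawn from the listed genes and matched on mean expression, a description of these libraries among called genes. EOMES and LHX1 reach a value of 1 only in the PB-Tfcp2l1ΔCP2 library; over all 5 listed genes, with no filter, the median was 1.17, at percentile 99.5.

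The listed genes of the endoderm list went in the same direction, at low values. Of 17 definitive and visceral endoderm genes, 4 were listed and all 4 were higher. SOX17 went from 0.06 to 0.89 (16.0-fold, 5.15 to 80.1) and GATA6 from 0.06 to 0.61 (10.8-fold, 4.34 to 34.4). FOXQ1 had 1 read in the control and 30 in the PB-Tfcp2l1ΔCP2 library (29.3-fold, 4.88 to 1197). FOXA2, a forkhead factor of the endoderm, had no read against 21, at least 6.84-fold higher against a floor of 3 counts per library. That floor leaves out the counting error of the 21 reads, and the exact 95% interval starts at 5.09. None of the 4 reached a value of 1, so no list median was formed on the log2(value + 1) scale. GATA5, of the same family as GATA6 but outside the list and chosen after its values were seen, was lower (0.99 to 0.29).

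Among 14 Activin/Nodal/TGF-beta targets, 3 were listed, all higher. Besides CER1 these were CYR61 (7.53 to 18.0, 2.38-fold, 2.12 to 2.69) and CTGF (10.8 to 22.9, 2.11-fold, 1.91 to 2.33). CYR61 and CTGF are matricellular genes. With 3 members no list median was formed. CER1 is in both this list and the streak list, so the lists are not independent. The WNT/beta-catenin list had 2 of 20 genes listed, SP5 (0.07 to 0.83, 12.4-fold, 3.93 to 62.7) and T, both higher. The only BMP target listed, MSX2, went from 0.75 to 2.42 (3.24-fold, 2.24 to 4.79). MSX2 and TFAP2A (0.11 to 0.53, 4.01-fold, 1.98 to 8.97) were the 2 listed genes of 17 in the non-neural ectoderm and neural crest list. The immediate early genes EGR1 (1.27 to 3.76) and JUN (5.92 to 13.6) were also higher, 2.96-fold (2.33 to 3.79) and 2.29-fold (2.05 to 2.56).

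The listed pluripotency genes were lower. Of 22 naive pluripotency genes 3 were listed, all lower: DPPA3 (Gene ID 359787), a maternal factor gene, at 5.08 against 1.92 (2.67-fold lower, 1.88 to 3.84), and the placental-type alkaline phosphatase genes ALPPL2 (22.0 against 10.5, 2.10-fold lower, 1.91 to 2.32) and ALPP (1.46 against 0.56, 2.62-fold lower, 1.80 to 3.90). ALPP and ALPPL2 are near-identical copies, and how reads were divided between them is uncertain. Of 21 core pluripotency genes 1 was listed, ZFP42 (Gene ID 132625), also called REX1, at 5.08 against 1.99 (2.53-fold lower, 2.05 to 3.14). No gene of the 15 primed pluripotency genes was listed. On the log2(value + 1) scale with median-of-ratios scaling these differences shrank to -0.31 for DPPA3, -0.04 for ALPPL2, -0.20 for ALPP and -0.26 for ZFP42. That factor rests on called genes only, so the shrinkage follows from its construction. The LIF/STAT3 list had 2 of 12 genes, BCL6 (4.92 against 1.20, 4.11-fold lower, 3.31 to 5.15) and BCL3 (4.60 against 2.10, 2.19-fold lower, 1.70 to 2.84). NCAM1 was the only 1 of 22 neuroectoderm genes listed, at 2.32 against 1.07.

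In the glycolysis and hypoxia list 2 of 19 genes were listed and both were lower, BNIP3, a mitophagy receptor gene (40.2 against 15.9, 2.53-fold lower, 2.30 to 2.79), and PFKFB4, a regulator of glycolysis (7.54 against 3.30, 2.54-fold lower, 2.22 to 2.91). The stress gene DDIT4, an inhibitor of mTORC1 signalling, was at 63.5 against 13.7. The other listed gene of the integrated stress response list, the cystine transporter gene SLC7A11, went the opposite way (2.07 against 4.34, 2.09-fold higher, 1.87 to 2.34). The p53 target GDF15 was at 4.5 against 2.19 (2.06-fold lower, 1.54 to 2.78). COL1A1, which is in both the extracellular matrix and the fibroblast list, was at 41.6 against 18.0 (2.31-fold lower, 2.20 to 2.42), and COL6A3 at 1.79 against 0.59 (2.96-fold lower, 2.43 to 3.62); they were the 2 listed of 17 matrix genes. Matrix genes outside the list, chosen after their values were seen, went both ways: TNC (0.33 against 1.62) and EFEMP1 (3.35 against 6.79) were higher, and LAMA4 (0.83 against 0.26) and MATN4 (0.53 against 0.06) were lower. COL1A1 was the only 1 of 12 fibroblast markers listed.

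Among genes with a value of 5 or more in the higher library, large increases on the log2(value + 1) scale besides CER1 were in the potassium channel genes KCNK9 (Gene ID 51305; 0.28 to 5.91, 21.0-fold, 12.6 to 38.1) and KCNH5 (0.39 to 5.28, 13.9-fold, 9.85 to 20.2), the cancer-testis gene MAGEA4 (0.54 to 6.73, 12.6-fold, 8.06 to 20.6) and HES3 (3.26 to 18.4, 5.62-fold, 4.12 to 7.81). Other large increases were in HRASLS (5.33 to 22.5), the cholesterol exporter gene ABCA1 (3.20 to 11.7, 3.67-fold, 3.39 to 3.98), PHF21B (6.71 to 19.6), the retinoic acid hydroxylase gene CYP26A1 (2.05 to 6.90, 3.35-fold, 2.68 to 4.23), AMOTL2 (2.82 to 8.72), CDX4 (1.84 to 5.73), DHRS2 (5.54 to 14.3), and BOLA2 and BOLA2B. The last pair are copies with identical values (4.44 to 11.3) and count as 1 measurement. By difference in value, SREBF1, which encodes a lipid synthesis regulator, was the largest increase (24.5 to 52.0, 2.13-fold, 2.03 to 2.23).

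The largest decreases after NMU were in ODC1, the rate-limiting enzyme of polyamine synthesis (79.0 to 17.2), DDIT4, the cytochrome gene CYP2B6 (17.9 to 3.56, 5.08-fold lower, 4.43 to 5.85), the neuronal pentraxin gene NPTX1 (33.8 to 7.50) and ARRDC3 (6.63 to 0.90, 7.37-fold lower, 5.92 to 9.27). For ODC1, DDIT4 and NPTX1 the p-values were too small to give reads, so these 3 have no counting interval; the ratios of their values were 4.60, 4.63 and 4.51. CYP2B6 has a closely similar pseudogene, and how reads were divided between them is uncertain. The glycoprotein hormone gene STC1 (16.5 to 3.49, 4.72-fold lower, 4.18 to 5.34), SMIM24 (18.5 to 5.23), the lactate transporter gene SLC16A3 (18.4 to 5.46, 3.36-fold lower, 2.92 to 3.87), SLC16A9 (6.15 to 1.5), BHLHE40 (6.36 to 1.58), S100A10 (52.1 to 20.3), the retinoic acid receptor gene RARG (13.7 to 5.33) and the list members BNIP3 and COL1A1 completed the 15 largest. By difference in value, LGALS1, which encodes galectin-1, was the largest decrease (127 to 63.0, 2.02-fold lower, 1.85 to 2.20). Its direction turned under median-of-ratios scaling. That factor rests on called genes only and moves a gene 2-fold lower to about no difference, so the turn says nothing of LGALS1 in particular.

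**Figure D2:**
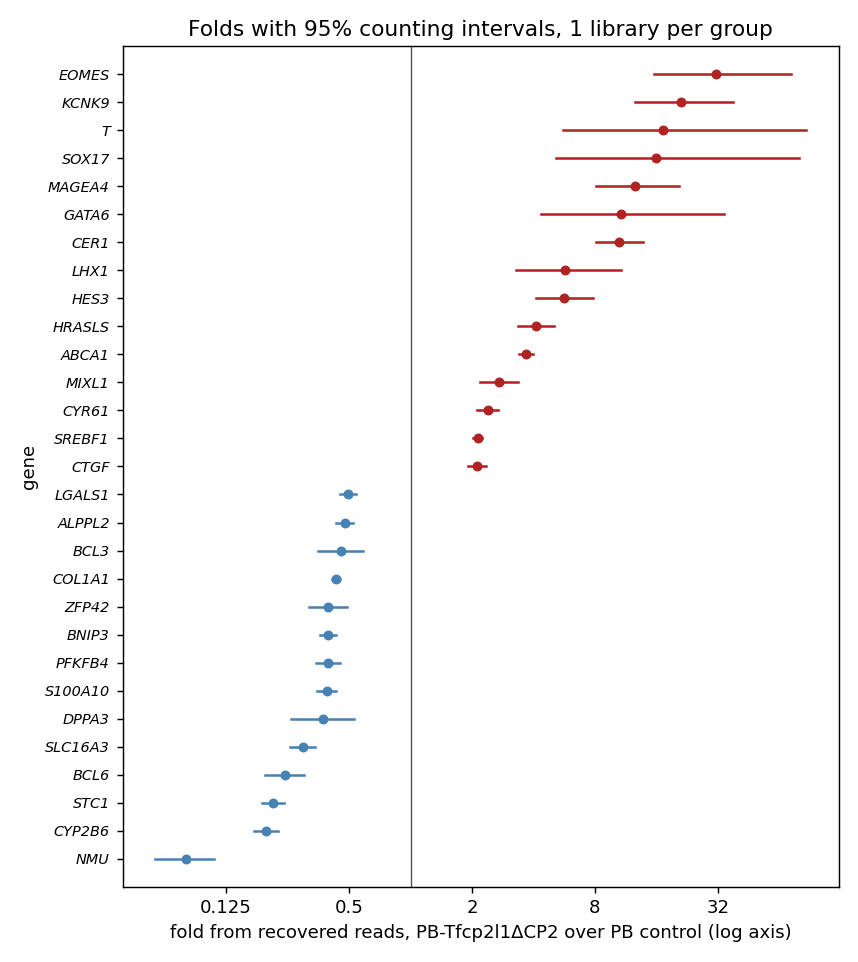
Fold of PB-Tfcp2l1ΔCP2 over PB control from recovered reads (x axis, log scale, no unit) for 29 genes (y axis). Points are folds and lines are 95% counting intervals, with 1 library per group; red marks the 15 higher genes and blue the 14 lower ones, and the grey line is no difference. The intervals of EOMES (15.6 to 73.2) and MIXL1 (2.20 to 3.35) do not overlap. All 29 genes come from rows selected as called, so an interval clear of the grey line restates that selection.

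Of the 30 gene lists, 14 had no listed member: primed pluripotency, mesoderm, trophoblast, FGF/ERK targets, the CP2/grainyhead family, the NuRD complex, DNA methylation, cell cycle, cholesterol synthesis, adhesion, histone, mitochondrially encoded, ribosomal protein and housekeeping genes. The values of these genes were not analysed here, so nothing is said of differences below the thresholds of the table. Over all lists 30 of 428 genes were listed, 17 higher and 13 lower.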

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

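All alternatives on recovered reads, on the total of the listed genes, without a pseudocount, and without unnamed or shared rows were chosen after seeing the data; the others were planned. No paired analysis was possible because each group had 1 library. The counts of genes at least 2-fold apart (49 higher, 49 lower) moved with most settings: 147 and 11 with median-of-ratios scaling, 91 and 21 with the total of the listed genes, 72 and 87 with a pseudocount of 0.5, 8 and 11 with one of 5, 25 and 32 with values of 5 or more, 111 and 154 at 1.5-fold, 7 and 6 at 4-fold, 201 and 224 with no pseudocount and no filter, and 153 and 189 on recovered reads of at least 50, with a 95%, a 99% or no counting interval, an equality that the selection of the table on these reads fixes. Without unnamed, read-through and shared rows they were 34 and 37. Removing the filter moved nothing, because a value below 1 cannot be 2-fold apart on this scale. The scalings shift every log2 ratio by 1.03 and 0.34 upward at high values, and the shift of median-of-ratios scaling follows from its construction: no listed gene lies within 2-fold, so the median ratio falls on a called gene. LGALS1, lower in the main values, was then at 0.021 and so reversed. A counting interval of 99% or none had been planned for counts; the values have no interval, so these settings were run on recovered reads as added alternatives. The authors' deposited calls were 201 and 224 at each FDR tried, which the selection of the table fixes. The median of the streak list (1.52, over 4 genes) was 1.92 and 0.67 with pseudocounts of 0.5 and 5, and 1.70 as a mean. Without a filter it was over 5 genes, at 1.17, or 3.39 without pseudocount and filter. Under both scalings T also passed the filter, so these medians were over 5 genes as well. They were 2.11 with median-of-ratios scaling and 1.47 with the total of the listed genes, both above the 1.17 of the same 5 genes unscaled. A filter at 5 left the streak list with too few genes. Without pseudocount and filter the endoderm list had a median of 4.34, at percentile 98.3 among the listed genes. Of the 40 named lower genes 9, LGALS1 included, lay within 0.1 of 0 under median-of-ratios scaling: the others were ABCG4 (-0.0077), GDF15 (-0.0082), IL6R (-0.015), ALPPL2 (-0.04), NCAM1 (-0.06), CNTFR (-0.08), CCNA1 (-0.08) and BCL3 (-0.08). Depth limits the low genes most: T, SOX17 and GATA6 rest on 3 to 5 control reads.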

Other observations

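The tests in this part, and its gene groups other than the streak, endoderm, Activin/Nodal/TGF-beta, glycolysis and hypoxia, and cholesterol synthesis lists, were chosen after the values were seen. Genes known to respond to liver X receptors, which sense oxysterols, were listed as 5 of 12: ABCA1, ABCG1 (0.39 to 1.78, 4.56-fold, 95% counting interval 2.99 to 7.19), MYLIP (7.55 to 15.8, 2.08-fold, 1.88 to 2.31) and SREBF1 were higher and ABCG4 lower (0.99 to 0.48, 2.05-fold lower, 1.41 to 3.01), while no cholesterol synthesis gene was listed. Of 10 genes known to respond to YAP/TEAD, 5 were listed and all 5 were higher: CTGF, CYR61, AMOTL2, THBS1 (1.68 to 4.14, 2.47-fold, 2.15 to 2.84) and ANKRD1 (no read against 17, at least 5.54-fold higher against a floor of 3 counts per library, with an exact 95% interval from 4.03). CTGF and CYR61 are also in the Activin/Nodal/TGF-beta list.

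Of 12 further genes known to respond to hypoxia, 7 were listed and all 7 were lower in the PB-Tfcp2l1ΔCP2 library. Besides STC1, SLC16A3, BHLHE40 and DDIT4 these were ANGPTL4 (2.5 to 0.72, 3.56-fold lower, 2.37 to 5.50), PPFIA4 (5.03 to 1.80, 3.08-fold lower, 2.75 to 3.45) and FUT11 (4.58 to 2.04, 2.28-fold lower, 1.78 to 2.92). The first 4 are among the largest decreases named above. Since the 12 genes were chosen after the values were seen, their direction is no separate support for that of BNIP3 and PFKFB4. Of 7 subunits and partners of IL6-family receptors, 2 were listed and both were lower: CNTFR (2.83 to 1.29, 2.22-fold lower, 1.62 to 3.07) and IL6R (1.33 to 0.64, 2.01-fold lower, 1.54 to 2.63). With median-of-ratios scaling the 7 further hypoxia genes ran from -1.15 for DDIT4 to -0.11 for FUT11 on the log2(value + 1) scale. BNIP3 was at -0.30 and PFKFB4 at -0.14. With the same scaling CNTFR was at -0.08 and IL6R at -0.015, close to no difference. This scaling rests on called genes only and moves all genes by 1 factor. Which genes come near 0 therefore follows from their starting difference and is no check of any of them.

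The 9 listed genes of the streak and endoderm lists were all higher. Library scaling as the whole cause would move each gene by 1 factor, but the lower bound of EOMES was 4.67 times the upper bound of MIXL1. These bounds are the extremes of the 9 intervals, and a scaling error on top of real differences is not excluded. Since the table was selected on these reads, it holds no separate test of counting error. It stays open whether the cells responded to Tfcp2l1ΔCP2 or whether this culture held more differentiated cells for another reason; with 1 culture per group these cannot be told apart, and the 9 listed genes go with either.

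Genes known from cleavage-stage embryos and from cells with DUX4 were listed as 9 of 20, with 8 lower and 1, TRIM49D1, higher. Single genes included CCNA1 (8.63 to 3.98, 2.17-fold lower, 1.81 to 2.60) and KDM4E (1.53 to 0.55, 2.79-fold lower, 1.90 to 4.19), and the copies TRIM43 and TRIM43B were 2.74-fold (1.99 to 3.83) and 2.46-fold (1.79 to 3.41) lower. How reads were divided among the near-identical TRIM copies, listed or not analysed here, stays open. A few cells of the control culture in a cleavage-like state could give the 8 lower genes as well, and bulk values of 1 library per group cannot tell that from a lower level in all cells.

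In 31 rows 1 library had no read. Of these, 58.1% (18 rows, exact lower bound 39.1%) were gene models without a name, read-through rows or rows that share a place or copy with another row, against 16.0% of the other 394 rows. TRIM34 (no read against 23) and TRIM6-TRIM34 (30 against none) show the pattern: their summed reads differed 0.75-fold (0.42 to 1.33). Of the 18 rows, 11 are gene models without a name. Their place was not known, so a shared place was not shown for them. The 394 other rows were not matched on read number. Reads given to another model of the same place are therefore only a possible explanation for such rows. The 13 rows outside the 18, FOXA2 and ANKRD1 among them, carry a gene name and were not found to share a place or copy with another listed row. Copies outside the listed rows were not looked for, so the same explanation stays possible for some of the 13. No biological explanation was tested.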
